A study of Mus musculus with 94 samples.

How the data were processed

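The series set out to compare transcriptomes and chromatin of mice exposed to air pollution with those of mice fed a high-fat diet. It holds 94 samples: 68 RNA libraries, 12 ATAC libraries and 14 OMNI libraries of liver, the last being another preparation for accessible chromatin. Groups were taken from the sample titles and treatment labels, which do not spell out FA or PM.

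For RNA the authors deposited a count per gene symbol for each library, after trimming with cutadapt, alignment to mm10 with STAR and counting with featureCounts, per the submitters' processing notes, which give no versions. Tables of 21 libraries held 50508 features and those of 47 held 50417, with 91 features in the longer table alone, and the 50417 shared ones were used. For chromatin the deposited count per region covers 139567 regions shared by all 26 libraries, after trimming with cutadapt and alignment to mm10 with BWA, per the submitters' processing notes. Region lengths ran from 120 to 4568 bp (median 168), and 0.53 to 1.43% of the non-zero region counts were odd, as when both ends of a read pair are counted. How regions were called is not stated there. Replicate 1 of the LIVER Cess group held no counts and was left out. Total counts per library, in units of 1e6, ran from 29.84 to 91.28 in RNA, 1.26 to 1.73 in ATAC and 0.7 to 5.69 in OMNI.

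Each tissue and preparation was fitted with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr (minimum count 10, minimum total 15), quasi-likelihood dispersions and tests on group means, and Benjamini-Hochberg adjustment with calls at adjusted p under 0.05. FA, PM and HFD were fitted together, FA22 and Cess apart, and the difference between the cessation effect and the exposure effect was tested as a contrast of the 4 groups. CPM are TMM-scaled, and sums of marker lists are CPM of total counts. Standard errors are the size of the estimate over the root of its quasi-likelihood F.

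In all 57 gene lists holding 830 genes (1 of them not among the shared symbols) were fixed beforehand and tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists of at least 5 measured genes. Over 19 comparisons camera made 214 calls in 685 tests, and with a correlation estimated per list it made 0, so the latter p is given beside each call. Calls within a list were also adjusted over the list alone.

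Genes were named by a rule. It takes the 5 largest rises and falls among called genes with a mean of at least 1 CPM, groups that do not overlap and a name that is not a clone, predicted gene or pseudogene. It adds, for up to 6 lists per comparison with a camera call or at least 2 called members, up to 4 members of smallest adjusted p. It always takes Arntl, Dbp, Nr1d1 and Per2, with Ucp1 and Dio2 in BAT, Lep, Adipoq and Adgre1 in WAT, Pdk4 and Ucp3 in QUAD, Agrp, Npy and Pomc in HYPO, and Srebf1, Scd1, Pck1, Cyp7a1, Cyp1a1, Hdac2 and Ep300 in LIVER. With 10 or fewer calls all are named, and with none the 3 of smallest p in each direction. PM against HFD and the differences of effects take genes named elsewhere and up to 3 rises and falls. For regions it takes the 4 largest gains and losses with a mean of at least 20 counts and groups that do not overlap, and called regions within 1 kb of an always-taken gene. Not every gene that the rule allows is printed, and some are not reported here.

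Regions were assigned to genes with RefSeq gene intervals of GRCm38.p6, which is mm10: a region belongs to a gene if it lies within 1 kb of either end of the interval, and the most accessible such region was used for expression comparisons, with 5 kb as an alternative and 10000 shuffles for p. Of the count symbols, 34626 were found among these intervals and 47562 among a list of gene names. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and GenomicRanges 1.54.1, were used for the rest.

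The gene test was tested on simulated counts drawn from each feature's mean and dispersion over the fitted libraries, with 100 features changed 2-fold and 100 changed 4-fold. In LIVER PM vs FA (16145 genes) edgeR recovered 54 and 90 of these, in QUAD PM vs FA (17078) 46 and 76, in BAT PM vs FA (16553) 15 and 65, in HYPO PM vs FA (20065) 13 and 59, and in WAT PM vs FA (20194) 13 and 60. In LIVER Cess vs FA22 (15910) it recovered 71 and 94, in WAT Cess vs FA22 (17912) 0 and 0, in ATAC PM vs FA (37407 regions) 24 and 75, in OMNI PM vs FA (31337) 23 and 67, and in OMNI Cess vs FA22 (42180) 22 and 73. For the difference of effects it recovered 54 and 80 in LIVER (17367 genes), 0 and 7 in WAT (21235) and 3 and 31 in OMNI (50729 regions). False calls were at most 14, in LIVER PM vs FA. The likeness of PM and HFD effects was set against 10 simulations of unchanged groups and against FA libraries split into 2 sets.

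Replicate numbers were checked as a possible pairing by correlating the deviations of same-numbered libraries from their group means. In no set did all same-numbered pairs exceed r = 0.1, so the numbers were used as a block only in an alternative fit. Other alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors, total counts for regions, no low-count filter, only the 2 compared groups, leaving out each library, fry for lists, and 5 kb. The lists, naming rule, tests and these alternatives were chosen before the data were examined. Leaving out libraries with markers of other tissues, a loess offset and thinning to equal depth were chosen after seeing the data.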

Results

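Gene counts were held for 68 RNA libraries from 5 mouse tissues: brown adipose tissue (BAT), hypothalamus (HYPO), liver (LIVER), skeletal muscle (QUAD) and white adipose tissue (WAT). Counts over regions of accessible chromatin were held for 26 liver libraries, 12 titled ATAC and 14 titled OMNI. The arms are named by their titles: FA (chow), PM (chow with PM exposure), HFD (high-fat diet), and a later set of FA22 (chow, with the number 22 in the title) and Cess (chow, PM exposure, then its cessation). Libraries per arm were 3 FA, 3 PM and 3 HFD in BAT, 4, 3 and 4 in HYPO, LIVER and WAT, 4, 3 and 3 in QUAD, and 4, 4 and 4 in ATAC. The later set held 4 FA22 and 3 Cess libraries in LIVER (a 4th Cess library held no counts), 4 and 4 in WAT, and 3 and 4 in OMNI, where the earlier set had 3 FA and 4 PM. Total counts per library, in units of 1e6, were 29.84 to 91.28 in the RNA libraries (mean 51.26), 1.26 to 1.73 in ATAC and 0.7 to 5.69 in OMNI. Values of single genes and regions are CPM (counts scaled to a library total of 1e6) as mean ± SD, and changes are log2 fold changes with their standard error (SE).

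In liver, PM exposure against FA asked what the exposure did to hepatic expression. Rgs16, a regulator of G protein signalling, rose from 7.18 ± 2.70 CPM (n = 4) to 35.0 ± 8.14 CPM (n = 3), a log2 fold change of 2.29 (SE 0.28, adjusted p = 0.0166), with each PM library above each FA library. Pck1, the rate-controlling enzyme of gluconeogenesis, fell from 3714 ± 643 to 1512 ± 38.6 CPM, a log2 fold change of -1.30 (SE 0.14, adjusted p = 0.00764), with each PM library below each FA library. These were the only genes of 16448 that edgeR called, against 793 at an unadjusted p under 0.05 and 28 called by DESeq2. With replicate number as a block edgeR called 0. Without PM replicate 1 or PM replicate 2 no gene was called (Rgs16 2.19 and 2.18, Pck1 -1.28 and -1.30), and without FA replicate 1, 2 or 4 there was 1, since Rgs16 did not pass (2.21, 2.30 and 2.11). Among genes that did not pass, the clock activator Arntl had a log2 fold change of -1.15 (SE 0.25, adjusted p = 0.452), the cytokine-signal inhibitor Socs3 -1.17 (SE 0.21, adjusted p = 0.27), the bile acid synthesis enzyme Cyp7a1 1.68 (SE 0.53) and the clock output gene Dbp 1.10 (SE 0.37). The lipogenic genes Srebf1 (0.21) and Scd1 (0.14), the dioxin-inducible Cyp1a1 (0.66), the deacetylase gene Hdac2 (0.01), the acetyltransferase gene Ep300 (-0.12), Nr1d1 (0.15) and Per2 (0.18) did not pass either.

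As groups in the same liver comparison, the acute phase genes were called lower by camera (adjusted p = 1.35e-09, and adjusted p = 0.687 with an estimated correlation). Of 17, 0 passed edgeR over all genes and 3 were lower adjusted over the list alone, with Saa2 at -2.08 (SE 0.78) and Lbp, the lipopolysaccharide binding protein, at -0.41 (SE 0.10). The extracellular matrix genes were also called lower (adjusted p = 1.63e-08, and 0.687 with an estimated correlation), with 0 of 24 genes passing over all genes and 0 adjusted over the list alone. Timp1, a metalloproteinase inhibitor, was at -2.13 (SE 0.77). Cholesterol synthesis was called higher (adjusted p = 0.00191, and 0.825 with an estimated correlation), with 0 of 23 genes passing by either adjustment and Msmo1, a sterol oxidase, at 0.44 (SE 0.15). Glucocorticoid targets, with Tat at -0.64, and heat shock proteins, with Hsph1 at -0.74, were called lower, each at adjusted p = 0.687 with an estimated correlation.

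The high-fat diet against FA in liver asked what the diet did to the same tissue. Cyp3a11, a major drug-metabolising P450, fell from 4827 ± 560 to 330 ± 39.4 CPM (log2 fold change -3.87, SE 0.21, adjusted p = 1.57e-06, 4 against 4 libraries that did not overlap). Cyp7a1 rose by 3.16 (SE 0.53), the lipogenic regulator Srebf1 by 1.25 (SE 0.18) and Rgs16 by 4.08 (SE 0.29), to 121.7 ± 37.4 CPM. Pck1 fell by 0.95 (SE 0.13). Among 787 genes higher and 686 lower of 16448 (1473 in all), the others of the 5 largest rises with at least 1 CPM were Gldn (4.99, SE 1.02), the clock repressor Ciart (4.49, SE 0.48), Tff3 (4.45, SE 0.66) and the steroid hydroxylase Cyp17a1 (3.90, SE 0.44). The other large falls were the nuclear receptor Nr4a1 (-4.04, SE 0.60), the clock gene Npas2 (-3.87, SE 0.40), Cyp3a16 (-3.59, SE 0.32) and the retinoic acid hydroxylase Cyp26a1 (-3, SE 0.49). Scd1 (0.41, SE 0.17), Nr1d1 (0.05), Hdac2 (0.01), Ep300 (0.32) and Cyp1a1 (-0.40) did not pass, but Scd1 did without HFD replicate 3 (0.55). The count was 3119 without HFD replicate 2, 909 without FA replicate 1 and 797 without FA replicate 2.

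Sterol synthesis genes were among the gene groups that changed in liver on the high-fat diet. Of 23 cholesterol synthesis genes 12 were higher over all genes and 20 adjusted over the list alone (adjusted p = 0.254 with an estimated correlation), among them Msmo1 at 1.13 (SE 0.14) and the squalene synthase gene Fdft1 at 0.73. Interferon response genes were higher for 8 of 20 (14 adjusted over the list alone, adjusted p = 0.254 with an estimated correlation), with Ifit1 at 1.31 (SE 0.14), Ifi44 at 1.12, Ifit3 at 0.93 and the RNA sensor Ddx58 at 0.75. Genes of xenobiotic metabolism under the receptors CAR and PXR were lower for 8 of 18 and higher for 3 (8 and 5 adjusted over the list alone, adjusted p = 0.254 with an estimated correlation), with Cyp2c55 at -2.59, Cyp2c29 at -1.20 and Cyp3a25 at -0.95 beside Cyp3a11. Of 19 unfolded protein response genes 6 were lower (11 adjusted over the list alone, with 1 higher, adjusted p = 0.254 with an estimated correlation), with Creld2 at -1.40, the chaperones Hyou1 at -1.29 and Hspa5 at -0.87, and Manf at -1.03. The acute phase genes were lower for 5 of 17 (6 adjusted over the list alone, adjusted p = 0.3615 with an estimated correlation), with Socs3 at -1.60, Orm2 at -1.26, Orm1 at -0.83 and Lbp at -0.58. Ribosomal protein genes were lower for 2 of 26 by both adjustments (adjusted p = 0.468 with an estimated correlation), Rpl10a at -0.43 and Rpl4 at -0.31. These 2 did not pass without any one of FA replicates 1 to 4 (Rpl10a -0.40 to -0.45, Rpl4 -0.29 to -0.33), nor without HFD replicate 3 (-0.38 and -0.28) or 4 (-0.34 and -0.26), and Rpl10a nor without HFD replicate 1 (-0.47).

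**Figure D1:**
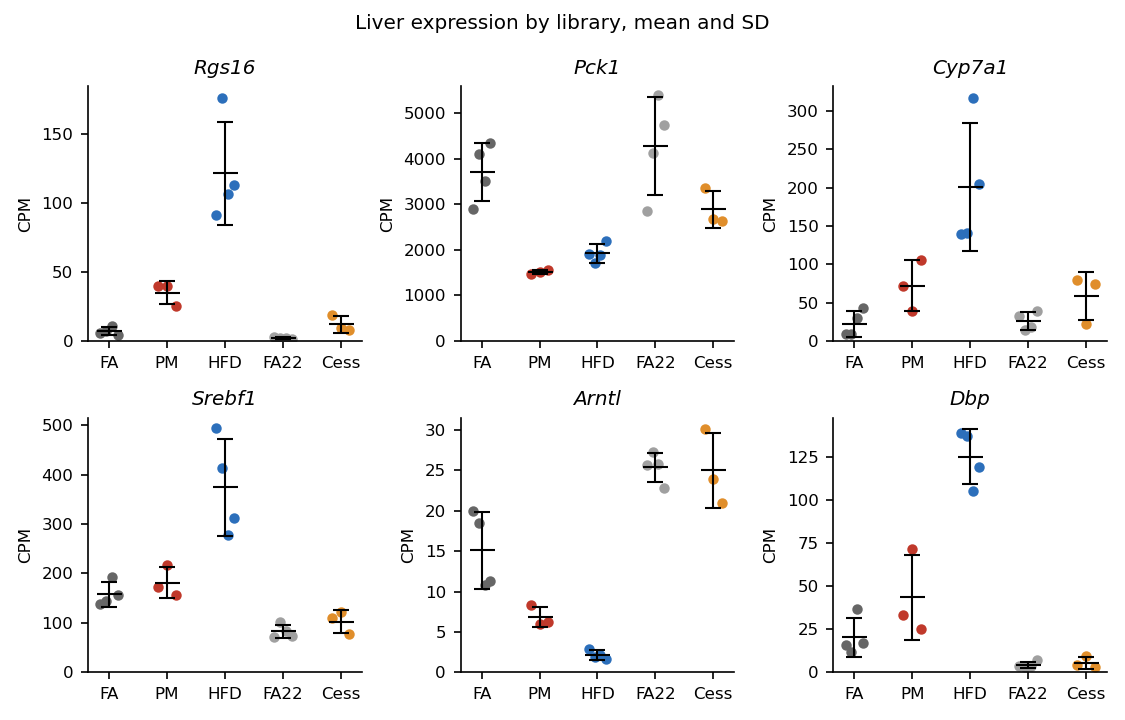
CPM of 6 liver genes by arm (mean and SD as bars, 1 point per library, 5 arms). Pck1 lies at 1512 ± 38.6 CPM in PM against 3714 ± 643 in FA, and Rgs16 at 35.0 ± 8.14 against 7.18 ± 2.70.

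Clock genes changed in several tissues on the high-fat diet. In liver 9 of 20 were higher and 4 lower over all genes (12 and 6 adjusted over the list alone, adjusted p = 0.291 with an estimated correlation), with Arntl at -2.82 (SE 0.25), Npas2 at -3.87 (SE 0.40), Dbp at 2.62 (SE 0.36) and the repressor Per2 at 1.98 (SE 0.26). In muscle 4 were higher and 1 lower (13 and 3 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation), with Dbp at 1.23 (SE 0.15), Per2 at 1.44 (SE 0.20) and Npas2 at -2.89 (SE 0.39). In muscle Dbp did not pass without HFD replicate 1 (1.17) or 3 (1.20), Per2 without HFD replicate 1 (1.53), 2 (1.55) or 3 (1.21) or FA replicate 3 (1.40), and Npas2 without HFD replicate 3 (-2.83). In WAT Arntl fell by 0.89 (SE 0.17), while Dbp (0.78) and Per2 (0.46) did not pass, nor did Arntl without HFD replicate 2 (-0.86) or 4 (-0.79). In BAT Arntl fell by 1.61 (SE 0.30) and Dbp rose by 2.02 (SE 0.33), while Per2 (-0.34) did not pass. Across the 20 genes the log2 fold changes of LIVER, QUAD, WAT and BAT correlated pairwise at r = 0.61 to 0.87 over 6 tissue pairs, and genes are not independent replicates. The same pairs had 10 to 17 of 20 genes with the same sign. In HYPO 1 clock gene was higher and 9 lower (1 and 12 adjusted over the list alone, adjusted p = 0.627 with an estimated correlation), Nr1d1 at -1.05 (SE 0.22) and Per2 at -1.13 (SE 0.26), and -0.62 without FA replicates 1 and 2, left out after seeing the data. Npas2 was at 38.53 and 155.4 CPM in those libraries, 14.14 and 12.85 in FA replicates 3 and 4 and 6.67 to 10.39 in HFD. HYPO correlated with the 4 other tissues at r = 0.29 to 0.47.

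**Figure D2:**
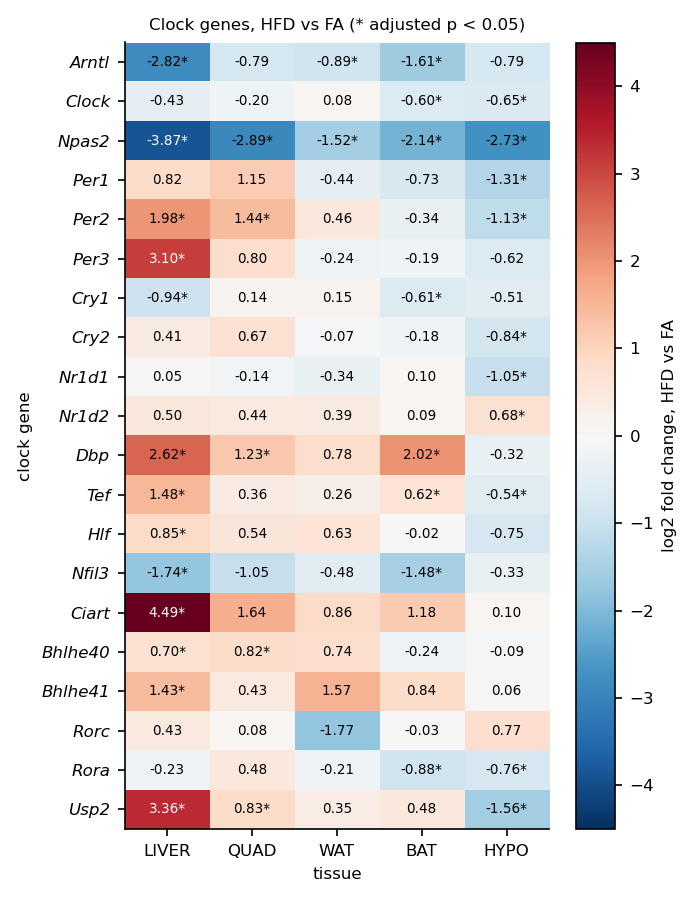
Log2 fold change of 20 clock genes on the high-fat diet against FA in 5 tissues, with an asterisk at adjusted p under 0.05. Arntl is at -2.82 in liver, -1.61 in BAT and -0.89 in WAT, and Dbp at 2.62, 2.02 and 0.78.

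PM against HFD in liver asked where the exposures part. Of 16448 genes 321 were higher in PM and 362 lower (683 in all). Cyp3a11 was higher in PM by 3.67 (SE 0.21), Npas2 by 2.87 and the metalloprotease-like Adam11 by 2.73 (16.8 ± 0.715 against 2.55 ± 0.75 CPM). Tff3 was lower by -4.81, Cyp17a1 by -4.08 and the guanylate cyclase Gucy2c by -4.01. The count was 2991 without HFD replicate 2, 427 without HFD replicate 3, 313 without HFD replicate 4, 151 without PM replicate 1 and 134 without PM replicate 3. It was 255 with replicate number as a block, 211 with only the 2 compared groups and 1431 by DESeq2. Gucy2c did not pass without HFD replicate 1 (-3.56) or PM replicate 1 (-4), 2 (-4.13) or 3 (-3.88).

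In muscle edgeR called 18 genes with the diet and DESeq2 218. The fatty acid transporter Slc27a2 fell from 1.93 ± 0.703 CPM (n = 4) to 0.0545 ± 0.0142 CPM (n = 3), a log2 fold change of -5.14 (SE 0.49, adjusted p = 0.00216), with each HFD library below each FA library. Igfn1, a muscle sarcomere protein gene, rose by 1.68 (SE 0.24), Mest by 1.87 (SE 0.26), the oxytocin receptor Oxtr by 2.48 (SE 0.39) and the small GTPase Rab15 by 2.62 (SE 0.37). The lipoprotein gene Apoc1 fell by 2.52 (SE 0.41), Pon1 by 2.20 (SE 0.31) and the class I gene H2-Q10 by 2.12 (SE 0.30). Each of these except Slc27a2 lost its call without 1 library. That was so for Igfn1 without HFD replicates 1, 2 and 3 and FA replicate 3 (1.61 to 1.75), Mest without HFD replicates 2 and 3 and FA replicates 1 and 3 (1.53 to 1.85), Oxtr without HFD replicates 2 and 3 and FA replicates 1 to 3 (2.03 to 2.52), and Rab15 without HFD replicates 1, 2 and 3 (2.41 to 2.75). It was so for Apoc1 without HFD replicates 1 to 3 and FA replicate 1 (-2.40 to -2.65), Pon1 without HFD replicates 1 to 3 and FA replicate 3 (-1.89 to -2.41), and H2-Q10 without HFD replicates 1 to 3 and FA replicate 1 (-1.93 to -2.35). The fuel switch kinase Pdk4 (0.10, SE 0.25), Ucp3 (0.07), Arntl (-0.79, SE 0.16) and Nr1d1 (-0.14) did not pass, but Arntl did without FA replicate 4 (-0.92). In all 11 genes were higher and 7 lower of 17405 (18), against 168 with replicate number as a block, 96 without the low-count filter, 10 without HFD replicate 1, 7 without HFD replicate 2, 3 without HFD replicate 3, 31 without FA replicate 2 and 75 without FA replicate 4. Of 15 hepatocyte markers 0 passed over all genes and 15 were lower adjusted over the list alone (adjusted p = 0.535 with an estimated correlation), and their summed CPM was 13.3 to 15 in the HFD libraries and 26.2 to 292 in the FA libraries. Without FA replicate 4 the liver-rich Ahsg (-4.53), Apoa1 (-5.33), Apoa2 (-4.52) and Ttr (-6.44) passed. Whether the falls of Slc27a2, Apoc1, Pon1 and H2-Q10 come from muscle or from liver RNA in the FA libraries was not tested.

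With PM in muscle, edgeR called 0 of 17405 genes, with 379 at an unadjusted p under 0.05 and 4, all lower, called by DESeq2. With replicate number as a block, 5 were called higher and 12 lower (17). The genes of smallest p that did not pass were the clock genes Bhlhe40 (0.50, SE 0.11) and Dbp (0.47, SE 0.15), and the liver-rich Apoa4 (-7.09, SE 1.55), Arg1 (-3.98, SE 0.91) and Cyp3a11 (-3.62, SE 0.85). The lung genes Scgb1a1 and Sftpc lay at 1.65 ± 2.13 and 1.18 ± 1.26 CPM in PM (n = 3), at 1.40 ± 0.52 and 1.03 ± 0.28 CPM in HFD (n = 3), and had no counts in FA. PM replicate 2 held 4.06 and 2.50 CPM and PM replicate 1 none, and against HFD (0.24 and 0.20, neither called) they were at -1.61 and -0.98 without PM replicate 2. Hepatocyte markers were lower for 0 of 15 over all genes and for 10 adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). Respiratory chain genes were called higher by camera with 0 of 32 passing (adjusted p = 0.672 with an estimated correlation). Between PM and HFD, Npas2 was higher in PM by 2.92 (SE 0.40), Slc27a2 by 3.72 (SE 0.50) and the clock-linked protease Usp2 lower by -0.84 (SE 0.11), of 4 genes in all. 1 was called without HFD replicate 1 and 0 without any of the other PM and HFD libraries (Npas2 2.55 to 3.45, Slc27a2 3.46 to 3.91, Usp2 -0.79 to -0.89).

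White adipose tissue on the high-fat diet gained macrophage and sterol transcripts. Atp6v0d2, a proton pump subunit of lysosome-rich macrophages, rose from 2.43 ± 1.53 to 59.5 ± 42.9 CPM (log2 fold change 4.61, SE 0.75, adjusted p = 0.0136, 4 against 4 libraries that did not overlap), Gpnmb rose by 4.15 (SE 0.70), Itgax by 2.87 (SE 0.59) and Lgals3 by 2.14 (SE 0.43). They were among 5 of 19 macrophage markers higher over all genes and 10 adjusted over the list alone (adjusted p = 0.814 with an estimated correlation). The adipose hormone Lep rose by 2.44 (SE 0.47), and Adipoq (-0.50, SE 0.20) and Adgre1 (1.05, SE 0.38) did not pass. Cholesterol synthesis genes were higher for 6 of 23 (16 adjusted over the list alone, adjusted p = 0.548 with an estimated correlation), with Insig1 at 1.89 (SE 0.31), Nsdhl at 1.69 and Lss at 1.47. Cell cycle genes were higher for 4 of 20 (10 adjusted over the list alone, adjusted p = 0.814 with an estimated correlation), with Mki67, a marker of dividing cells, at 1.24 (SE 0.27). Mesothelial markers were lower for 4 of 10 (5 adjusted over the list alone, adjusted p = 0.591 with an estimated correlation), with Wt1 at -2.22 and Upk3b at -1.98. Of the hepatocyte markers, 11 of 15 were lower (14 adjusted over the list alone, adjusted p = 0.548 with an estimated correlation). Their summed CPM was 145 to 240 in HFD and 405 to 1410 in FA. Itgax did not pass without HFD replicate 2 or 4 or FA replicate 1, 2 or 4 (2.20 to 2.90). Lgals3 did not without HFD replicate 2 or FA replicate 1, 3 or 4 (2.03 to 2.17), Lep without HFD replicate 2 or 4 or FA replicate 3 (2.15 to 2.43). Mki67 did not without HFD replicate 2 or 4 or FA replicate 2, 3 or 4 (1.09 to 1.23), and Upk3b without HFD replicate 2 or 4 or FA replicate 3 (-1.86 to -1.90).

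Counts in the same WAT comparison rested on single libraries. In all 489 genes were higher and 583 lower of 20638 (1072). The count was 81 with replicate number as a block, 139 without HFD replicate 2, 1795 without HFD replicate 3, 224 without HFD replicate 4, and 640, 540, 394 and 514 without FA replicates 1, 2, 3 and 4. The largest rises were the phosphate carrier Slc34a2 (8.13, SE 1.92), Gpr50 (7.17, SE 1.44), the choline carrier Slc5a7 (6.80, SE 1.09), the integrin Itgad (6.79, SE 0.99) and the sperm-binding Crisp2 (6.27, SE 1.46). The largest falls were Serpina6 (-5.89, SE 1.43), Hamp2 (-5.33, SE 1.27), Cyp2j5 (-5.18, SE 1.07), Prss51 (-4.88, SE 0.83) and Cyp3a11 (-4.75, SE 0.96). Summed hepatocyte markers were higher in each FA library than in each HFD library. Whether the falls of Serpina6, Hamp2, Cyp2j5 and Cyp3a11 come from adipose tissue or from liver RNA in the FA libraries was not tested. Slc34a2 did not pass without HFD replicate 1 or 2 or any one FA library (6.07 to 8.65), Gpr50 without any one FA library (6.78 to 7.77), and Crisp2 without HFD replicate 2 or 4 or any one FA library (5.92 to 6.61). Serpina6 did not pass without HFD replicate 2 or 4 or FA replicate 2 or 4 (-5.25 to -6.05), Hamp2 without HFD replicate 1, 2 or 4 or FA replicate 2 or 4 (-4.74 to -6.30), Cyp2j5 without HFD replicate 2 or 4 or FA replicate 4 (-4.27 to -5.76), Cyp3a11 without the same libraries (-4.42 to -5.18), and Prss51 without HFD replicate 4 (-4.68). The summed CPM of epididymal epithelium markers was 20300 in HFD replicate 3 and 11.7 to 85.1 in the other HFD libraries, and 12 of these 12 genes were higher adjusted over the list alone with 0 over all genes (adjusted p = 0.89 with an estimated correlation). Against HFD, PM had 407 genes higher and 561 lower (968), with Prss51 at 5.34, Cyp2j5 at 4.92, Gpr50 at -7.73 and the muscle growth inhibitor Mstn at -7.04. That count was 0 with replicate number as a block, 240 without HFD replicate 2, 1502 without HFD replicate 3, 132 without HFD replicate 4, and 35, 57 and 0 without PM replicates 1, 2 and 3. In it Prss51 did not pass without HFD replicate 4 or any one PM library (4.88 to 5.51), Cyp2j5 without HFD replicate 1, 2 or 4 or any one PM library (4.23 to 5.51), Gpr50 without any one PM library (-7.18 to -8.13), and Mstn without HFD replicate 2 or 4 or any one PM library (-6.41 to -9.64).

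In WAT under PM exposure the respiratory chain genes were lower as a group. camera called them lower (adjusted p = 2.13e-09, and 0.614 with an estimated correlation), and 20 of 32 were lower adjusted over the list alone, with 0 over all genes. Ndufa5, a complex I subunit, had a log2 fold change of -0.60 (SE 0.15) and Cox5a of complex IV -0.46 (SE 0.11). edgeR called 0 of 20638 genes, with 3174 at an unadjusted p under 0.05 and 60 called by DESeq2. Among the genes of smallest p, which did not pass (each at adjusted p = 0.288) were the costimulatory receptor Tnfrsf18 (1.00, SE 0.18), Reps2 (0.74) and Xxylt1 (0.54), and Tsfm (-0.68) and Trappc4 (-0.49). Ribosomal protein genes were called lower by camera (adjusted p = 0.895 with an estimated correlation) and epididymal epithelium markers higher (adjusted p = 0.83 with an estimated correlation), each with 0 genes passing by either adjustment. Lep (0.40), Adipoq (-0.12), Adgre1 (0.06), Arntl (-0.09) and Dbp (0.85) did not pass.

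**Figure D3:**
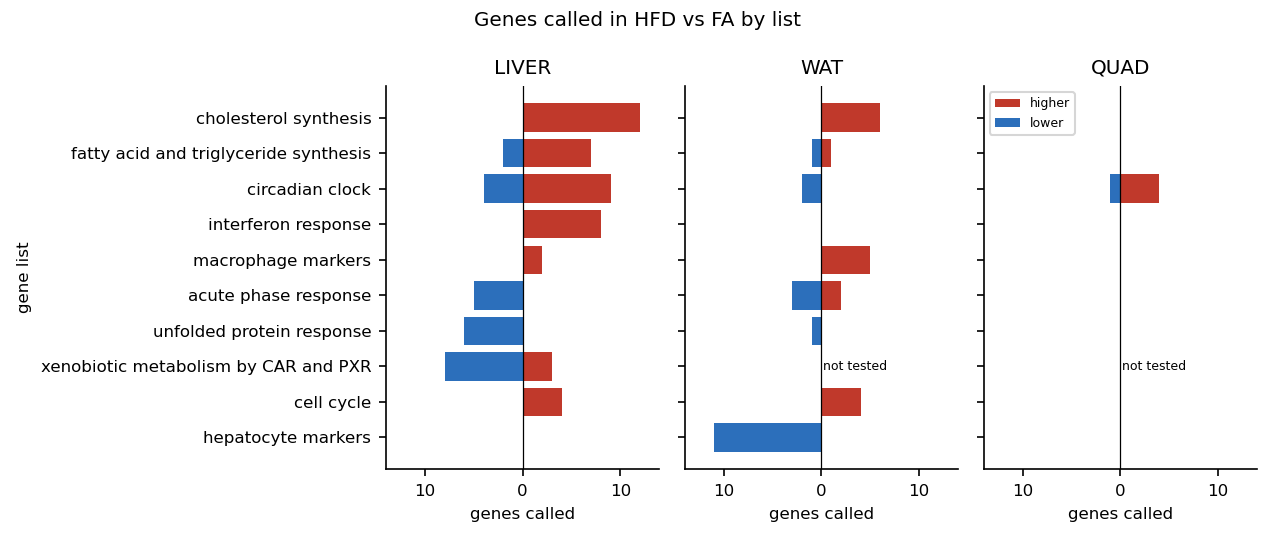
Number of genes called higher (to the right) and lower (to the left) by edgeR on the high-fat diet against FA in 3 tissues for each of several gene groups, with a note where a group was not tested. Cholesterol synthesis has 12 genes higher in liver and 6 in WAT, and hepatocyte markers 11 lower in WAT.

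Brown adipose tissue libraries of the high-fat diet arm held fewer chromatin-methylation transcripts. A library batch that follows this arm cannot be told apart from the diet. Kmt2a, a histone H3 lysine methyltransferase, fell from 59.4 ± 5.23 to 18.8 ± 4.56 CPM (log2 fold change -1.66, SE 0.21, adjusted p = 0.00299, 3 against 3 libraries that did not overlap), the DNA demethylase Tet2 fell by 1.98 (SE 0.25) and Kmt2d by 1.64 (SE 0.27), among 14 of 25 methylation enzymes lower (15 adjusted over the list alone, adjusted p = 0.556 with an estimated correlation). Schwann cell markers were lower for 8 of 10 by both adjustments (adjusted p = 0.553 with an estimated correlation), with Ncmap at -2.67 and the myelin gene Prx at -2.11. Cell cycle genes were higher for 8 of 20 (9 adjusted over the list alone, adjusted p = 0.556 with an estimated correlation), with the mitotic kinase Cdk1 at 2.74 (SE 0.62). Respiratory chain genes were higher for 10 of 32 by both adjustments (adjusted p = 0.809 with an estimated correlation), with Atp5c1, an ATP synthase subunit, at 1.01 (SE 0.16). The uncoupling protein Ucp1 (0.37, SE 0.63), the thyroid hormone activator Dio2 (-2.17, SE 0.74), Nr1d1 (0.10) and Per2 (-0.34) did not pass. Ucp1 was at 520.4 CPM in HFD replicate 1, 4062 and 4507 in the other HFD libraries and 1610 to 3215 in FA, and passed at 0.87 without HFD replicate 1, while Dio2 passed at -2.56 without FA replicate 1.

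Liver-rich transcripts were higher in the same BAT comparison. Of the hepatocyte markers, 14 of 15 were higher by both adjustments (adjusted p = 0.556 with an estimated correlation), with Alb at 4.62 and Serpina1b at 4.69, and their summed CPM was 762, 95.6 and 174 in the HFD libraries against 51.5 to 73.1 in FA. Acute phase genes were higher for 8 of 16 (10 adjusted over the list alone, adjusted p = 0.556 with an estimated correlation), with Saa3 at 5.31 (SE 0.94). The largest rises were Apoc4 (7.30, SE 1.40), Cyp3a11 (6.12), the iron hormone Hamp (5.90) and Mup20 (5.74). The largest falls were Rps27rt (-4.83, SE 0.29), the mitochondrial tRNA genes mt-Tq (-4.43) and mt-Tp (-3.51), the potassium channel Kcna1 (-3.61) and Egr1 (-3.37). In all 2208 genes were higher and 2232 lower of 16944 (4440), against 2123 without HFD replicate 3, 1729 without FA replicate 2 and 2423 without FA replicate 3. Egr1 did not pass without HFD replicate 2 (-3.45) or 3 (-3.23) or FA replicate 2 (-1.42). PM against HFD gave 2464 higher and 2311 lower (4775), led by the muscle myosin Myh8 (6.45) and Hamp (-5.30, and -3.38 without HFD replicate 1 and PM replicate 1, left out after seeing the data), with 2359 without HFD replicate 3, 2737 without PM replicate 1 and 2480 without PM replicate 3. Myh8 did not pass without HFD replicate 2 (5.87) or 3 (6.17) or PM replicate 1 (6.64) or 2 (5.10). Summed CPM of skeletal muscle markers was 71500 in HFD replicate 1 and 5640 in each of replicates 2 and 3, 58600, 36500 and 23400 in PM, and 15500 to 23200 in FA. Myh8 was at 33.5, 100.3 and 1.292 CPM in PM replicates 1, 2 and 3 and at most 1.223 in HFD.

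In BAT with PM exposure, sterol synthesis and adipocyte genes were called lower as groups and muscle genes higher. camera called the cholesterol synthesis genes lower (adjusted p = 5.15e-15, and 0.0857 with an estimated correlation), with 9 of 22 lower adjusted over the list alone and 0 over all genes. The squalene epoxidase Sqle had a log2 fold change of -0.98 (SE 0.19) and Pmvk -0.70 (SE 0.16), each with 3 PM libraries below 3 FA libraries. Fatty acid synthesis was called lower too (adjusted p = 0.45 with an estimated correlation), with Scd2 at -1.11 (SE 0.36), Pnpla3 at -0.79 and 0 of 18 passing by either adjustment. The skeletal muscle markers were called higher (adjusted p = 0.664 with an estimated correlation) with 0 of 12 passing by either adjustment, 12 of 12 positive, and Ttn at 2576 ± 1063 CPM in PM and 1138 ± 269.9 in FA. Adipocyte genes were called lower (adjusted p = 0.437 with an estimated correlation), with 1 of 16 lower adjusted over the list alone and 0 over all genes, and Adrb3 at -0.64 (SE 0.15). edgeR called 0 of 16944 genes, with 721 at an unadjusted p under 0.05 and 5 called by DESeq2. Besides Sqle, the genes of smallest p were Ucp3 (1.00, SE 0.19), Ccdc86 (0.93), the nucleolar Nop58 (0.73), Ccng2 (-0.83) and Slc5a3 (-0.67), each at adjusted p = 0.993. Ucp1 (-0.31), Dio2 (0.78), Arntl (-0.45), Dbp (0.81) and Per2 (-0.64) did not pass.

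In hypothalamus, mitochondrial and ribosomal transcripts were higher in the high-fat diet libraries, where a library batch cannot be told apart from the diet. mt-Co2, a mitochondrially encoded oxidase subunit, rose from 7.28 ± 2.16 to 269 ± 124 CPM (log2 fold change 5.21, SE 0.43, adjusted p = 5.70e-05, 4 against 4 libraries that did not overlap), mt-Co3 rose by 4.99, mt-Atp6 by 4.03, Cox5a by 2.09 (SE 0.26) and Rpl19 by 2.56 (SE 0.27). Respiratory chain genes were higher for 27 of 32 (29 adjusted over the list alone, adjusted p = 0.627 with an estimated correlation), ribosomal protein genes for 23 of 26 by both adjustments (adjusted p = 0.627 with an estimated correlation) and mitochondrially encoded genes for 11 of 13 by both (adjusted p = 0.557 with an estimated correlation). Methylation enzymes were lower for 15 of 25 and higher for 1 (16 and 1 adjusted over the list alone, adjusted p = 0.627 with an estimated correlation), with Kmt2d at -2.12 (SE 0.21) and Tet3 at -1.56. The HFD libraries in HYPO had total counts, in units of 1e6, of 30.68 to 40.17 over a table of 50508 features, with 53.2 to 53.86% of their non-zero counts odd, and the FA and PM libraries 53.58 to 80.79 over 50417 features, with 42.36 to 43.9% odd.

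Transcripts of other tissues also differed in these HYPO libraries. Hepatocyte markers were higher in HFD for 13 of 15 by both adjustments (adjusted p = 0.627 with an estimated correlation), with Alb at 7.71 (SE 0.67). Cyp3a11, Fabp1, Mup20 and Serpina3k lay at 3.33 ± 2.02, 4.93 ± 3.07, 4.26 ± 2.65 and 5.46 ± 3.09 CPM in HFD and had no counts in FA. Adipocyte genes were higher for 9 of 16 by both adjustments (adjusted p = 0.627 with an estimated correlation), with Fabp4 at 9.87 (SE 1.20). Of the cortex and hippocampus markers 7 of 11 were lower by both adjustments (adjusted p = 0.733 with an estimated correlation), with summed CPM of 7410 and 3580 in FA replicates 1 and 2, 960 and 1010 in FA replicates 3 and 4 and 494 to 705 in HFD. Lower too were striatum markers for 7 of 10 (9 adjusted over the list alone, adjusted p = 0.883 with an estimated correlation). The largest falls were Ptprv (-6.75, SE 1.82), the activity-induced Egr3 (-6.23), Ankrd63 (-5.78), the channel gene Kcnh3 (-5.18) and Adnp (-5.16, SE 0.93). Of these, Egr3, Ankrd63 and Kcnh3 were at 82.17, 95.16 and 210.6 CPM in FA replicate 1 and 199.2, 387.6 and 307.1 in FA replicate 2, against at most 9.297 CPM in FA replicates 3 and 4, and Ptprv was at 23.35 in FA replicate 2 and at most 0.2399 in the other FA libraries. Without FA replicates 1 and 2, a choice made after seeing the data, Egr3 was at -2.08, Ankrd63 at -1.50, Kcnh3 at -1.26 and Ptprv, which did not pass, at -1.67. Ptprv was at -1.88 without FA replicate 2 alone. The feeding peptide genes Agrp (1.35, SE 0.98), Npy (-0.11) and Pomc (0.49) did not pass. In FA replicates 1 and 2 Agrp was at 0.6147 and 0.4788 CPM and Pomc at 10.66 and 1.973, against 6.218 and 9.027, and 702.5 and 154.6, in replicates 3 and 4. Pomc was at -0.41 without the first 2. In all 4146 genes were higher and 4182 lower of 20713 (8328), against 5469 without HFD replicate 2 and 5407 without HFD replicate 3.

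PM against HFD in HYPO gave 2083 genes higher and 3034 lower of 20713 (5117), with the cardiac actin Actc1 at 4.41, Adnp at 4.34 and the cardiac myosin Myh6 at 3.69. That count was 3018, 2845, 2786 and 8111 without HFD replicates 1, 2, 3 and 4, and 2395, 2395 and 2759 without PM replicates 1, 2 and 3. PM against FA gave 0 of 20713 by edgeR, with 1565 at an unadjusted p under 0.05 and 22 called by DESeq2. The genes of smallest p that did not pass (adjusted p = 0.648) were Cpne9 (2.25, SE 0.58), Cyp3a13 (2.14), Krt4 (5.74, SE 1.35), the activity-induced Nr4a3 (-1.46, SE 0.31) and Fosl2 (-1.35), and Tll1 (-1.35). Striatum markers were called lower by camera with 8 of 10 lower adjusted over the list alone and 0 over all genes (adjusted p = 0.579 with an estimated correlation), and their summed CPM was 13400 in FA replicate 2 and 373 to 495 in the other FA libraries. Genes for hypothalamic neuropeptides and receptors were called higher by camera with 0 of 22 passing by either adjustment (adjusted p = 0.579 with an estimated correlation), and their summed CPM was 456 and 413 in FA replicates 1 and 2 and 1610 to 4040 elsewhere. Agrp (0.21), Npy (-0.34), Pomc (-0.70), Arntl (-0.79) and Per2 (-0.53) did not pass. Pomc turned to 1.26 without FA replicate 3 and Agrp to -0.65 without FA replicates 1 and 2, where Arntl was at 36.21 and 64.94 CPM against 20.11 and 22.57 in replicates 3 and 4 and 19.17 to 23.16 in PM.

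The likeness of the PM and HFD effects was compared across genes with simulated unchanged groups, since both effects share the FA libraries. The correlation of log2 fold changes was 0.688 in QUAD (0.409 in the simulated groups), 0.583 in WAT (0.451), 0.397 in HYPO (0.448), 0.361 in LIVER (0.470), 0.127 in BAT (0.490) and 0.461 in ATAC (0.490). When the FA libraries were halved so that no library was shared, the mean correlation was 0.194 in QUAD, 0.370 in WAT, 0.160 in HYPO, 0.101 in LIVER and 0.0187 in ATAC. BAT had too few FA libraries. Rgs16 was higher and Pck1 lower in liver under both exposures. Genes are not independent replicates.

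After cessation, the question was whether liver and WAT still differed from their own FA22 group. In liver no gene passed: edgeR called 0 of 16125, with 2010 at an unadjusted p under 0.05 and 230 called by DESeq2. The count was 1 without FA22 replicate 1, 35 without FA22 replicate 2, 2 without FA22 replicate 3 and 52 without Cess replicate 4. Rgs16 was at 11.97 ± 6.08 CPM in Cess (n = 3) and 2.11 ± 0.846 CPM in FA22 (n = 4), a log2 fold change of 2.52 (SE 0.35, adjusted p = 0.12), and Pck1 at -0.57 (SE 0.18). The other genes of smallest p were the P450 genes Cyp2c38 (1.19, SE 0.18) and Cyp2c54 (0.38), the glucuronosyltransferase genes Ugt2b38 (-2.30, SE 0.35) and Ugt2b37 (-1.77), and Lrg1 (-0.73). Male-biased liver genes were called lower by camera (adjusted p = 5.72e-16, and 0.245 with an estimated correlation), with 0 of 13 over all genes and 9 adjusted over the list alone, among them Selenbp2 (-1.82, SE 0.37) and the pheromone carrier Mup20 (-0.83). Acute phase genes were lower for 0 of 17 over all genes and 10 adjusted over the list alone (adjusted p = 0.245 with an estimated correlation), with Saa1 at -2.09 (SE 0.35) and Hp at -0.62. Without Cess replicate 4, Rgs16 (2.75), Selenbp2 (-2.50), Ugt2b38 (-2.96), Ugt2b37 (-2.23), Mup20 (-1.02), Cyp2c38 (1.27), Cyp2c54 (0.42) and Lrg1 (-0.74) passed, and without FA22 replicate 2 so did Saa1 (-2.31), Hp (-0.70), Mup20 (-0.93), Ugt2b38 (-2.42), Cyp2c38 (1.29) and Lrg1 (-0.80). Cyp7a1 (1.16), Scd1 (0.79), Srebf1 (0.31), Arntl (-0.01), Dbp (0.35), Cyp1a1 (-0.10), Hdac2 (-0.02) and Ep300 (0.02) did not pass.

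Of 167 liver genes at an unadjusted p under 0.01 in PM against FA, 131 (78.4%) had the same sign in Cess against FA22, with r = 0.131 across 14844 genes. In WAT 262 of 613 (42.7%) did, with r = -0.12 across 17806 genes. Neither share was set against unchanged groups, and genes are not independent replicates. These shares thus do not decide whether an effect of PM lasted in either tissue. WAT after cessation had 0 of 18295 genes called by edgeR, with 452 at an unadjusted p under 0.05 and 0 by DESeq2. In simulated counts of this comparison edgeR recovered 0 of 100 2-fold and 0 of 100 4-fold changes, and DESeq2 3 and 54. The edgeR count of 0 thus does not show that WAT was unchanged. In WAT the genes of smallest p (adjusted p near 1 for each) were the kinase Bmx (1.19, SE 0.37), Kcng2 (1.75), Ighv5-17 (5.62, SE 1.70), Azgp1 (-1.89), the protease inhibitor Pzp (-2.14) and the gastric lipase Lipf (-1.70). Cell cycle genes were called higher by camera with 0 of 20 passing (adjusted p = 0.881 with an estimated correlation). Summed epididymal epithelium markers were 39600 and 47900 CPM in FA22 replicates 1 and 2 and 40900 CPM in Cess replicate 4. The difference between the cessation and exposure effects was tested directly and gave 0 genes by edgeR in LIVER (1419 at an unadjusted p under 0.05, 30 by DESeq2) and 0 in WAT (1236 and 43). It takes a batch between the earlier and later libraries to act alike on both arms of a set. In the liver fit the first principal component of the most variable genes parted these sets and held 99% of their variance. Of 100 simulated 2-fold and 100 simulated 4-fold differences, this test recovered 54 and 80 in LIVER and 0 and 7 in WAT. The simulated counts gave each gene the same mean in the earlier and later libraries. In LIVER, where these sets part, the recovery may therefore differ from that of the real test. In liver 1 gene was called without FA replicate 3. Pck1 differed by 0.71 (SE 0.24, adjusted p = 0.524) and Rgs16 by 0.22 (SE 0.47).

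Chromatin in the ATAC libraries differed at few regions. With PM against FA, 4 of 40946 regions were higher and 0 lower by edgeR, with 1756 at an unadjusted p under 0.05 and 0 called by DESeq2. They were chromosome 2 from 22587539 to 22590530 (mm10, within the myosin gene Myo3a, 698 ± 1159 against 94.2 ± 8.26 CPM, log2 fold change 2.89, SE 0.40, n = 4 and 4), chromosome 13 from 85126662 to 85127383 (3.23), chromosome 10 from 96077497 to 96077744 (3.70) and chromosome 12 from 97061377 to 97061739 (3.2). Without PM replicate 2 none was called, at 0.33, 0.87, 0.27 and 0.40. The high-fat diet gave 0 regions by edgeR, with 2999 at an unadjusted p under 0.05 and 74 by DESeq2, and 1 without FA replicate 2 or without HFD replicate 2. Between PM and HFD, the 4 regions were higher in PM, and regions near Anxa3 (chromosome 5 from 96846536 to 96847464, -1.59, SE 0.27) and near Plk5 (chromosome 10 from 80367934 to 80368339, -1.65, SE 0.28) were lower. Of these 6, the region near Anxa3 alone was called without PM replicate 2, when the region near Plk5 was at -1.48.

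The OMNI libraries differed at many regions with PM against FA. Among called regions within 1 kb of an end of the always-named genes, 3 were more accessible in PM: Per2 (chromosome 1 from 91459031 to 91459772, 0.59, SE 0.20, adjusted p = 0.0467), Dbp (chromosome 7 from 45704769 to 45705345, 0.78, SE 0.24) and Pck1 (chromosome 2 from 173152554 to 173153121, 1.00, SE 0.25). A region in both Thra and Nr1d1, called the Thra region below, was less accessible (chromosome 11 from 98768354 to 98768556, -1.74, SE 0.49). The Per2 region did not pass without any one FA library (0.58 to 0.67) or PM replicate 3 (0.61) or 4 (0.59). The Dbp region did not without FA replicate 1 (0.67) or 3 (0.85) or PM replicate 1 (0.67), Pck1 without FA replicate 3 (0.84), and the Thra region without FA replicate 1 or 3 or PM replicate 3 (-1.60 each) or 4 (-1.63). With replicate number as a block the Per2, Dbp and Thra regions did not pass. Per2 and Thra did not without the low-count filter, nor Per2 with total counts. The largest gains were on chromosome 14 from 95614491 to 95614664 (29.5 ± 8.83 CPM in PM, n = 4, and no counts in FA, n = 3), in the homeobox gene Pbx4 (chromosome 8 from 69843396 to 69843555, 5.31, SE 0.70), on chromosome 5 from 42176565 to 42176718 (4.67) and on chromosome 1 from 132784417 to 132784611 (4.23). The Pbx4 region had FA counts in replicate 3 alone and the chromosome 5 region in replicate 2 alone. The largest losses were 9578 bp from the cell cycle inhibitor Cdkn2a (chromosome 4 from 89264652 to 89264894, -2.47, SE 0.38), in the integrin gene Itgb7 (-2.30), near Adamtsl5 (-2.26) and in Pear1 (-2.20). In all 1645 regions were higher and 1942 lower of 34735 (3587), against 1810, 2377 and 1820 without FA replicates 1, 2 and 3 and 2124 without PM replicate 1. With replicate number as a block 1969 were called. The balance turned to more regions higher without FA replicate 1 (1038 and 772 lower) or 3 (1018 and 802), with no low count filter (1786 and 567) and in DESeq2 (1951 and 1802). It was near even without FA replicate 2 (1199 and 1178) or PM replicate 2 (1581 and 1578) or 3 (1230 and 1170).

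After cessation the OMNI libraries differed at 2509 regions higher and 1713 lower of 46625 (4222), and at 1358 without FA22 replicate 2 and 1784 without FA22 replicate 3. The gene-start regions of Per2 (1.05, SE 0.19), Dbp (1.27, SE 0.23), Pck1 (0.75, SE 0.19) and Nr1d1 (chromosome 11 from 98775152 to 98775581, 1.19, SE 0.25) were more accessible in Cess than in FA22. Pck1 did not pass without FA22 replicate 2 (0.74). The largest gains were on chromosome 3 from 152701599 to 152701814 (4.22, SE 0.27), in the cadherin gene Cdh9 (3.68), at the chromosome 1 region that also gained with PM (3.61) and on chromosome 16 from 3114479 to 3114673 (3.56). The largest losses were on chromosome 11 from 13815960 to 13816819 (-2.82), on chromosome 15 from 31175839 to 31176683 (-2.75), in the glutamate receptor gene Grin2b (-2.74) and in Nedd4l (-2.70). With total counts in place of TMM the split was 1599 higher and 2792 lower, with a median log2 shift of -0.12 over all regions. Of the regions called with PM, 3433 of 3535 tested in both (97.1%) had the same sign after cessation and 1596 (45.1%) were called there too, with r = 0.68 over 33768 regions. Whether a batch that follows the arms in both OMNI sets adds to this likeness was not tested. Of those higher with PM 990 of 1603 (61.8%) were called again, with a median log2 fold change of 1.18 with PM and 0.92 after cessation. Of those lower 606 of 1932 (31.4%) were, with medians of -1.11 and -0.58. Regions chosen by their PM values can give smaller medians in another set without any change, so these medians do not show a decline. The difference between the effects gave 0 regions by edgeR (2158 at an unadjusted p under 0.05, 0 by DESeq2), and 2 without Cess replicate 1. For simulated differences of 2-fold and 4-fold, this test recovered 3 and 31 of 100 regions each.

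**Figure D4:**
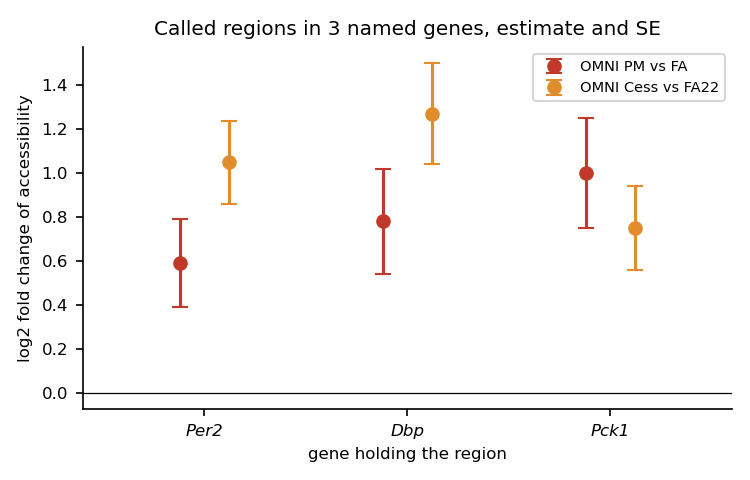
Log2 fold change and SE of the gene-start regions of Per2, Dbp and Pck1 in the OMNI libraries, for PM against FA and Cess against FA22. Estimates run from 0.59 for Per2 to 1.00 for Pck1 with PM, and from 0.75 for Pck1 to 1.27 for Dbp after cessation.

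The preparations differed in these results. Of 3162 regions called with PM in OMNI and tested in ATAC, 1598 (50.5%) had the same sign in ATAC, and the correlation over 30471 regions was 0.026. Of 3458 regions called with PM in ATAC or after cessation in OMNI, 1677 (48.5%) had the same sign in both. The correlation there was 0.025 over 35561 regions. The Pck1 gene-start region gained accessibility in OMNI with PM (1.00) while Pck1 transcripts fell by 1.30. Genes with higher and lower regions in OMNI with PM differed in their median expression change by 0.015 (p = 0.11 by permutation of the labels across genes), and after cessation by 0.007 (p = 0.49, permutation). Genes called higher and lower in liver on the high-fat diet differed in their median ATAC change by 0.018 (p = 0.38, permutation), each on the log2 scale.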

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

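Of the tests in this part, the loess offset, the thinning of OMNI counts, the comparison of OMNI with ATAC, the comparison of HFD with PM calls, the splits at an unadjusted p and the clock correlations between tissues were chosen only after the result was seen. In groups of 4 libraries, the library farthest from the rest was tested for its distance from them in total counts, marker sums and named genes. That picked out 35 of 344 groups, where chance picks about 1 in 20 (17.2): 23 of 146 for marker lists and totals, and 12 of 198 for named genes.

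In white adipose tissue, Cess replicate 2 had a total of 80.17 (in units of 1e6, others 37.89 to 42.69), and summed CPM of 12100 for hepatocyte markers (others 213 to 1070), 102 for pancreatic acinar markers (0.234 to 1.64), 5980 for mesothelial markers (788 to 1020) and 7210 for mammary and skin epithelium markers (47.8 to 1070). Cess replicate 4 had 40900 for epididymal epithelium markers (83.3 to 181) and Cess replicate 1 had 666 for skeletal muscle markers (34.1 to 77). HFD replicate 3 had 20300 for epididymal epithelium markers (11.7 to 85.1), 611 for mammary and skin epithelium markers (5 to 61.5) and 7.685 CPM of the sperm protein gene Crisp2 (0.1371 to 0.9564). HFD replicate 1 had 2510 for erythroid markers (535 to 854), HFD replicate 2 a total of 42.08 (44.19 to 44.52), and FA replicate 2 had 103 for mammary and skin epithelium markers (28.7 to 34.5) and 30.35 CPM of Tsfm (23.42 to 23.83).

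In hypothalamus, FA replicate 2 had 13400 for striatum markers (373 to 495), 120 for T cell markers (5.06 to 11.6), 10.15 CPM of Cpne9 (7.872 to 8.2) and 23.35 CPM of Ptprv (0.123 to 0.2399). Adnp was at 37.4 CPM in FA replicate 3 (6.496 to 7.354) and at 1.227 in HFD replicate 4 (0.09646 to 0.1477). Krt4 was at 0.02999 CPM in FA replicate 4, with no counts in the other FA libraries. Dbp was at 43.19 CPM in HFD replicate 4 (56.3 to 58.31), and neutrophil markers were at 16.2 in HFD replicate 1 (6.59 to 7.49).

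In liver, HFD replicate 2 had 488 for stellate cell markers (530 to 532) and 45.4 for T cell markers (26.5 to 29.2), HFD replicate 3 had 898 for Kupffer cell markers (699 to 726) and HFD replicate 1 had 538 for erythroid markers (256 to 298). FA22 replicate 1 had 0.653 for pancreatic acinar markers (0.17 to 0.186), FA22 replicate 4 had 23.5 for skeletal muscle markers (16.1 to 17.1), and Cyp1a1 was at 1.099 CPM in FA replicate 3 (0.924 to 0.9494). In skeletal muscle, FA replicate 4 had 98 for T cell markers (4.04 to 5.95), 142.9 CPM of Nr1d1 (192.3 to 201.4) and 5.43 CPM of Mest (4.053 to 4.168), and Apoa4 was at 19.98 CPM in FA replicate 2 (0.5693 to 3.735). Among OMNI libraries, Cess replicate 2 had a total of 2.8 (1.44 to 1.65).

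The OMNI libraries differ at 3587 regions with PM, and the ATAC libraries of the same tissue at 4. Depth alone is argued against, since 1933 of the 3587 regions (53.9%) were still called with the same sign after thinning to the smallest total, and so is a trend with mean abundance, since 3652 were called with a loess offset. An accessibility change that both preparations measure is argued against as the cause of the set, since 50.5% of the called regions that were tested in ATAC (1598 of 3162) had the same sign there. A preparation batch that follows the OMNI arms would give the same 50.5% and stays open, as does a change in the animals of the OMNI libraries alone, which was not tested. Such a batch would have to follow the arms of the later OMNI set in the same direction. There 3433 of 3535 regions (97.1%) had the same sign after cessation.

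The HFD libraries differ from FA in 4440 genes in BAT and 8328 in HYPO, and the PM libraries in 0 by edgeR (721 and 1565 at an unadjusted p under 0.05, 5 and 22 by DESeq2). RNA carried over from liver may add hepatocyte transcripts, at a median of 0.22% of the liver level for 15 hepatocyte markers in BAT (0.13 to 0.617%) and 0.0616% in HYPO (-0.0168 to 2.26%), but as the whole cause it is argued against by genes with under 0.1 CPM in liver, which were 20.6% (853) of the genes higher in HYPO and 13% (288) of those higher in BAT. A library batch that follows the HFD arm cannot be told apart from the diet: of the genes called against FA, 55.6% in HYPO (4633) and 81.8% in BAT (3634) were called in the same direction against PM, as either would give, so an effect of diet stays open too. In HYPO such a batch exists at the counting step, where HFD libraries alone use the table of 50508 features. They hold 53.2 to 53.86% odd counts against 42.36 to 43.9% in FA and PM, and whether their lower totals give this was not tested.

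Log2 fold changes of 20 clock genes on the high-fat diet correlated between LIVER, QUAD, WAT and BAT with r from 0.61 to 0.87 over 6 tissue pairs, but 10 to 17 genes had the same sign in a pair, and Per2 was at 1.98 in LIVER, 1.44 in QUAD and -0.34 in BAT (genes are not independent replicates). The r of 0.87 between liver and muscle does not decide whether the diet acts on the liver clock alone. WAT after cessation, with no clock gene called, reached r = -0.77 with HFD in LIVER and -0.79 with HFD in QUAD. Calls were not confined to liver, since Dbp passed in QUAD (1.23) and BAT (2.02). PM against FA correlated too (r from 0.36 to 0.72 over the same pairs, and 0.89 between PM in LIVER and HFD in BAT), while Cess against FA22 in WAT had r from -0.69 to -0.83 with HFD in the 4 tissues. In that WAT comparison 4 libraries held markers of other tissues. Without them, a choice made after seeing the data, Arntl turned from 0.53 to -0.17, Nr1d1 from 0.08 to -0.04 and Dbp from -0.43 to 0.27. The correlations without these libraries were not computed, so the negative r may rest on them. Another hour of tissue collection in the HFD arm (lowest r 0.61), or in the FA arm that HFD and PM share (lowest r 0.36), may give such correlations and stays open, since no hour is given. A diet effect on the clock or on feeding times in all 4 tissues would do so too and was not tested.

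Other splits of the same libraries into groups of the same sizes were counted for each result. A share under 0.05 giving as many calls argues against chance for that result alone, with no adjustment for the number of results. The smallest share possible is 1 of 35. It was reached for the high-fat diet against FA in HYPO (8328 genes, highest other 1572), LIVER (1473, 0) and WAT (1072, 0), for PM against HFD in WAT (968, 286), and for OMNI regions with PM (3587, 2) and after cessation (4222, 53). In WAT PM against HFD 0 genes were called without PM replicate 3 or with replicate number as a block. Chance cannot be excluded for QUAD HFD against FA (2 of 35, 18 genes, highest other 27), LIVER PM against FA (2 of 35, 2 genes, 3) or PM against HFD in HYPO (2 of 35, 5117, 7220, in a split that puts HFD replicate 4 with PM) and LIVER (3 of 35, 683, 2866, HFD replicate 2 with PM). Nor can it for ATAC regions in PM against FA (23 of 35, 4, 7) and PM against HFD (3 of 35, 6, 12). For 3 against 3 the splits are too few for a share under 0.05: BAT HFD against FA (1 of 10, 4440 genes, highest other 0), BAT PM against HFD (1 of 10, 4775, 0), BAT PM against FA (10 of 10, 0, 0) and QUAD PM against HFD (1 of 10, 4, 0).

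Where the real split calls none by edgeR, every split gives as many and the count decides nothing about chance. That holds for PM against FA in HYPO (35 of 35, real 0, highest other 0), QUAD (35 of 35, 0, 3) and WAT (35 of 35, 0, 0), ATAC HFD against FA (35 of 35, 0, 1), and Cess against FA22 in LIVER (35 of 35, 0, 16) and WAT (35 of 35, 0, 6848). It holds too for the differences of effects in LIVER (80 of 80 drawn splits, 0, 12), WAT (80 of 80, 0, 5207) and OMNI (40 of 40, 0, 5337). The split of 6848 genes in WAT puts FA22 replicates 1 and 2 with Cess replicates 2 and 4, which points to a structure of the samples other than their arms, and the split of 5207 parts the later libraries in the same way. The split of 5337 OMNI regions keeps FA and PM apart and exchanges most FA22 and Cess libraries, so it adds the 2 effects of the arms.

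For the same comparisons, the genes or regions at an unadjusted p under 0.05 were compared between splits after their values were seen. The real split had the most of 35 in LIVER Cess against FA22 (2010, highest other 1847) and ATAC HFD against FA (2999, highest other 2544). It was matched or passed in WAT PM against FA (3174, 2 of 35 splits with as many, the real one included), HYPO (1565, 7 of 35) and QUAD (379, 34 of 35), in WAT Cess against FA22 (452, 17 of 35), and for the differences of effects in LIVER (1419, 6 of 80), WAT (1236, 13 of 80) and OMNI (2158, 15 of 40). DESeq2 called 230 in LIVER Cess, 74 in ATAC HFD, 60, 22 and 4 with PM in WAT, HYPO and QUAD, 0 in WAT Cess, and 30, 43 and 0 for the differences of effects.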

How the results depend on the processing

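Leaving out HYPO FA replicates 1 and 2, QUAD FA replicate 4, WAT HFD replicate 3 and BAT or WAT libraries with markers of other tissues, the loess offset and the thinning were chosen after seeing the data, and the other alternatives before. With DESeq2 size factors in place of TMM all 25 counts of calls stayed within 1.5 times, as did all 6 region counts with total counts, though OMNI Cess against FA22 then had 1599 regions higher and 2792 lower against 2509 and 1713 (a median shift of -0.116). Among named genes and regions that passed against FA or FA22, no direction reversed, while genes that did not pass could turn, as Pomc in HYPO PM against FA to 1.26 without FA replicate 3. For PM against HFD in WAT, Crisp1 and Spint4, which did not pass, were at -2.59 and -4.6 without PM replicate 1, the lowest, and turned to 5.07 and 4.13 without HFD replicate 3, the highest. Simulated 2-fold changes were recovered for 24 of 100 regions in ATAC and 23 in OMNI with PM, and for 54 genes in LIVER, 46 in QUAD, 15 in BAT and 13 in HYPO and WAT, and what part of this depth limits was not tested. For the values below the cause was not tested.

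The DESeq2 Wald test called, in PM against FA, 5 genes in BAT, 22 in HYPO, 28 in LIVER, 4 in QUAD, 60 in WAT and 0 ATAC regions. In HFD against FA it called 218 in QUAD, 2654 in WAT and 74 ATAC regions, in PM against HFD 1431 in LIVER, 42 in QUAD, 2835 in WAT and 2 ATAC regions, and in LIVER Cess against FA22 230. For differences of effects it called 30 in LIVER and 43 in WAT. The other 9 counts stayed within 1.5 times.

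With only the 2 compared groups fitted, edgeR called 5 in LIVER PM against FA, 2 in QUAD and 205 in WAT HFD against FA and 2715 in BAT. In PM against HFD it called 2746 in BAT, 211 in LIVER, 42 in QUAD and 554 in WAT. Fewer libraries inform the spread here. With no low-count filter it called 11 in LIVER PM against FA, 96 in QUAD and 687 in WAT HFD against FA, 12 in QUAD and 581 in WAT PM against HFD, 204 in LIVER Cess against FA22, 1 ATAC region with HFD, 2353 OMNI regions with PM (1786 higher and 567 lower), 60 genes for the difference of effects in LIVER and 3 regions in OMNI.

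With replicate number as a block, edgeR called 0 genes in LIVER and 17 in QUAD PM against FA, 168 in QUAD and 81 in WAT HFD against FA, 255 in LIVER, 70 in QUAD and 0 in WAT PM against HFD, 14 in LIVER Cess against FA22, 1 ATAC region and 1969 OMNI regions with PM and 1 region for the OMNI difference of effects. The block ended the calls of Rgs16 (2.21) and Pck1 (-1.21) with PM in liver and of the OMNI regions at Per2 (0.56), Dbp (0.80) and Thra, and turned Crisp1 to 1.84 and Spint4 to 0.8 in WAT PM against HFD. Without the filter the Per2 (0.77) and Thra (-1.54) regions were not called either, nor was the Per2 region with total counts (0.56).

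After leaving out 1 library at a time, the lowest and highest counts of genes against FA were 0 and 0 in BAT PM, 1729 and 5758 in BAT HFD, 5407 and 10356 in HYPO HFD, 0 and 2 in LIVER PM, 797 and 3119 in LIVER HFD, 3 and 75 in QUAD HFD and 139 and 1795 in WAT HFD. For PM against HFD they were 2359 and 6655 in BAT, 2395 and 8111 in HYPO, 134 and 2991 in LIVER, 0 and 1 in QUAD and 0 and 1502 in WAT, and for LIVER Cess against FA22 0 and 52. For regions they were 0 and 5 in ATAC PM, 0 and 1 in ATAC HFD and 1 and 7 in ATAC PM against HFD, 1810 and 3159 in OMNI PM and 1358 and 4014 in OMNI Cess. For differences of effects they were 0 and 1 in LIVER and 0 and 2 in OMNI.

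Without HYPO FA replicates 1 and 2, HFD against FA in HYPO gave 7842 genes, 6171 of them shared with the 8328. PM against HFD, which compares no FA library but shares the fit, gave 7943. Without QUAD FA replicate 4, HFD gave 75 in QUAD and PM against HFD 22. Without WAT HFD replicate 3, HFD gave 1795 and PM against HFD 1502 in WAT. Thinned to the smallest total, OMNI PM gave 2283 of 18859 regions tested (1108 higher and 1175 lower, 1933 shared with the 3587).

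Of the 214 gene list calls by camera, 0 held with an estimated correlation. Over all 685 list tests, fry called 75 by direction and 231 for change in either direction. Across FA libraries split into 2 sets, the correlation between the effects of PM and HFD was 0.1598 in HYPO, 0.1012 in LIVER, 0.1937 in QUAD, 0.3703 in WAT and 0.01867 in ATAC. With 5 kb in place of 1 kb, r between expression and accessibility across genes was 0.018, 0.044, 0.004 and 0.046, against 0.014, 0.031, 0.011 and 0.034, and the median expression difference between regions higher and lower after cessation was 0.015 (permutation p = 0.12) against 0.007 (permutation p = 0.49). Entered at an unadjusted p under 0.01, 78.4% of 167 liver genes had the same sign in PM against FA and Cess against FA22. Of the called genes 2 of 2 did. For OMNI regions the share was 96.6% against 97.1%.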

Other observations

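The gene lists named in this part were picked after their values were seen, and their tests were planned. In liver after cessation, edgeR called 0 genes (2010 at an unadjusted p under 0.05, 230 by DESeq2), and fry by direction and camera with an estimated correlation called 0 gene lists (fry called 14 for change in either direction), so the counts below are of genes adjusted over the list alone. Genes of xenobiotic metabolism by CAR and PXR were higher for 8 of 17 in Cess (adjusted p = 0.344 with an estimated correlation), with the P450 gene Cyp2b9 at a mean of 2.8 against 0.336 CPM (log2 fold change 3.05, SE 0.62, n = 3 and 4) and Cyp2c37 at 0.40 (SE 0.09). Fatty acid and triglyceride synthesis genes were higher for 6 of 17 (adjusted p = 0.344 with an estimated correlation), among them the malic enzyme Me1 (0.58, SE 0.12) and the elongases Elovl5 (0.45) and Elovl6 (0.35). Erythroid markers were lower for 6 of 6 (adjusted p = 0.245 with an estimated correlation), with the globins Hba-a1 at -1.75 (SE 0.51) and Hbb-bt at -2.11 (SE 0.58), and the male-biased P450 gene Cyp2d9 was at -0.46 (SE 0.08). None of these genes passed over all genes, but Cyp2b9 did without Cess replicate 4 (3.51), and Me1 (0.69) and Cyp2d9 (-0.50) did without FA22 replicate 2. In the difference of effects, male-biased liver genes were lower for 6 of 13 and genes of xenobiotic metabolism higher for 6 of 18, adjusted over the list alone (adjusted p = 0.238 with an estimated correlation for both), and 0 passed over all genes by edgeR (1419 at an unadjusted p under 0.05 and 30 by DESeq2).

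On the high-fat diet, male-biased liver genes were lower for 5 of 13 (6 adjusted over the list alone, with 1 higher, adjusted p = 0.3615 with an estimated correlation), and fatty acid and triglyceride synthesis genes were higher for 7 of 18 and lower for 2 (10 and 2 adjusted over the list alone, adjusted p = 0.291 with an estimated correlation). In BAT the mitotic kinases Plk1 (1.77, SE 0.43) and Aurkb (1.93, SE 0.48) and the nucleotide reductase subunit Rrm2 (1.00, SE 0.25) rose. Plk1 did not pass without HFD replicate 3 (1.65) or FA replicate 1 (1.49) or 3 (1.72), and Aurkb without HFD replicate 3 (1.81) or FA replicate 1 (1.72) or 3 (1.70). Rrm2 did not pass without HFD replicate 3 (0.82) or FA replicate 1 (0.99), 2 (1.00) or 3 (0.99). Endothelial markers in BAT were lower for 6 of 13 by both adjustments (adjusted p = 0.629 with an estimated correlation), and macrophage markers higher for 4 of 19 (8 adjusted over the list alone, adjusted p = 0.8095 with an estimated correlation). In HYPO, interferon response genes were higher for 9 of 20 and lower for 1 by both adjustments (adjusted p = 0.643 with an estimated correlation), and metal response genes higher for 7 of 12 by both (adjusted p = 0.627 with an estimated correlation).

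Summed CPM of neutrophil markers in skeletal muscle was 191 in HFD replicate 2 and 152 in PM replicate 2, and 1.91 to 17.8 in the other libraries. Summed CPM of B cell markers there was 540 in FA replicate 4 and 119 to 220 in the others. In WAT, 39.53% of the non-zero counts were odd in FA22 replicate 3 (total 91.28, in units of 1e6) and 39.76% in Cess replicate 2 (80.17). In BAT these shares were 34.69% in FA replicate 2 (77.0) and 34.43% in PM replicate 1 (70.59).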
